A study of Homo sapiens with 12 samples.

How the data were processed

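Total RNA of HaCaT cells, a spontaneously immortalised human keratinocyte line, was labelled with Cy3 and hybridised to 1-colour Agilent whole human genome oligonucleotide arrays, per the labels' protocols. Cells were left untreated or exposed for 2, 6 or 24 h to 1 of 3 dispersions of anatase titanium dioxide (TiO2), a white pigment and sunscreen mineral. The labels call these T-7, T-20 and T-200 after the average primary particle size of 7, 20 or 200 nm, with specific surface areas of 316, 66 and 10 m2/g. Each dispersion was a different centrifugal fraction in serum-containing medium, and the concentration applied was not given in the sources used here. A difference between sizes can therefore also hold a difference in fraction, aggregate size or dose.

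The deposited table held 41078 probes in 12 columns, 1 for each agent and exposure time, with no missing value, and every column was used. The labels give n = 3 for each sample while each has 1 column, so a column may be the mean of 3 arrays, which no label states. No signal level remained in the values. The authors' deposited values are taken here as log2 ratios of a sample to the untreated control of the same exposure time. The log base, the centring on the control and the direction (sample over control) are readings of the values, not statements of a label. With the direction turned, every sign and every split into higher and lower would turn with it. A natural log would make every log2 difference 1.44 times larger. The spread of the columns bears on the centring alone, while the base and the direction were assumed. The SD over probes was 0.18, 0.16 and 0.13 in the control columns of 2, 6 and 24 h, against 0.30 to 0.50 in the TiO2 columns. The column medians were 0.01, 0.01 and 0.01 in the control columns of 2, 6 and 24 h, 0.04, 0.10 and 0.13 for T-7, 0.08, 0.01 and 0.11 for T-20, and 0.04, 0.05 and 0.06 for T-200. The normalization behind them, the image software and its settings were not given in the sources used here.

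Probes were named through the platform's probe annotation. Of all probes, 29341 had 1 gene symbol, 33 had several and 11704 had none. The symbols gave 18646 genes, of which 7610 had 2 or more probes, and a gene's value was the mean of its probes. Probes without a single symbol entered the counts of probes and no gene. The number of arrays limits the precision, with 1 column per agent and time. Without a signal level dim and bright probes look alike, so what part dim probes play could not be judged.

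Tests were run in R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8). The main comparison was an additive model over all 12 columns with agent and exposure time as factors, fitted with lmFit and eBayes. It asks for a shift of an agent that the 3 times share, with 6 residual degrees of freedom and a prior of 2.47 for probes and 2.51 for genes. Adjusted p-values are Benjamini-Hochberg values over all probes or all genes, with 0.05 as the threshold. The times stand in for replicates (n = 3 times per agent). Nothing says that columns came from separate cultures, so p-values measure only the spread between these columns, which may be technical. All sizes shared 1 control column per time. A second model had a TiO2 term for each time, with the 3 sizes as stand-ins for replicates against 1 control column, which is assumed to vary as the sizes do and whose own spread is not measured. It also tested the difference of that term between 24 h and 2 h. Single columns were set against the control column of their time with no test. The numbers of genes at 2-fold or more are given beside the same number between TiO2 columns.

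Gene lists, 42 in number, covered pathways of keratinocytes and particle responses and markers of fibroblasts, melanocytes, leukocytes, endothelium and simple epithelium as signs of other cells. Of their genes and those of a fixed panel, 1158 of 1247 were measured. They were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists, with camera at an estimated correlation and fry beside it. In single columns a list's median was placed among 10000 random lists of the same size, matched in 20 bins on the mean absolute control value at the other times. Whether the control column lay apart from the TiO2 columns was tested with an exact one-sided permutation test over 64 choices of 1 odd column per time. After the results were seen, that test was added for the correlation of probes centred on the 4 columns of their time, and the lists were tested without ID1, ID2 and ID3.

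Genes were named by a rule. For each main comparison it takes up to 12 each way with an adjusted p under 0.05 and the same sign at every time. Where fewer than 5 passed, it takes the 5 largest each way with an unadjusted p under 0.01 and the same sign at every time, named as not passing. It adds the 5 largest each way in single columns, a fixed panel, and up to 4 members of a called list with the largest change. Genes named from the model with a TiO2 term per time, the members of its lists, and other genes given as such were chosen after their values were seen. The design, lists, naming rule, thresholds and first set of alternatives were chosen before the data were examined.

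Several steps departed from the plan because the values were ratios. The plan used values as deposited if column medians lay within 0.1 of each other and a shift to a common 75th percentile otherwise. They spanned 0.006 to 0.131, just outside that limit. Values were still kept as deposited, because the 75th percentile of a ratio grows with its spread (0.04 in the control column and 0.49 in the T-7 column of 24 h), and the shift is given as an alternative. The variance trend with intensity was dropped from eBayes, since the mean of a ratio is no intensity, and is an alternative too. Dim filters and floors had no level to act on. Random lists were matched on control spread in place of expression, and single columns were named from the less variable genes, those below the median control spread. The planned differences between exposure times (6 h minus 2 h, 24 h minus 2 h and 24 h minus 6 h) were not run, since a ratio to each time's own control has already removed the change with time. Other alternatives were quantile normalization, median centring, no time block, only the columns compared, each time or column left out, other fold limits, noisy probes left out and a test of the ratios against 0. Quantile normalization gives every column the same distribution. It thus widens the control columns (SD 0.13 to 0.18) towards the TiO2 columns (0.30 to 0.50). Calls that it adds or ends may come from that widening, which was not tested.

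The scripts were checked on simulated data with 200 changed features. For T-7 minus control, 38.8% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered among 18646 genes, with 11 false calls of 155. For probes of the same comparison the shares were 26.9%, 61.2% and 89.4% of 41078 tested, with 5 false calls of 123. In the model with a TiO2 term per time, 16.4%, 65.7% and 83.3% of simulated genes were recovered at 24 h, with 8 false calls of 118. In the real columns the error of that model also holds differences between sizes, with an SE of 0.87 for ID2 at 24 h. With the real T-7 column of 24 h set apart, 34 genes were called, as many as with the untreated column. The simulated shares and false calls of that model therefore cannot be carried over to the real columns. A proteasome list shifted 1.5-fold was recovered in the T-7 comparison with an adjusted p of 4e-68, and 0 other lists of 42 were called. The simulated noise was independent between genes. This check therefore cannot show how many lists are called falsely where genes are correlated.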

Results

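Gene expression was measured on 12 samples of HaCaT keratinocytes: untreated cells and cells exposed to TiO2 of 7 nm (T-7), 20 nm (T-20) or 200 nm (T-200) primary size, each at 2, 6 and 24 h. Every combination had 1 column of log2 ratios over 41078 probes, so no value has a replicate at its own time, and the 3 exposure times of an agent served as its repeats. The values carry no signal level and the concentrations applied are not in the labels. The study asked how the primary size of TiO2 particles changes gene expression in keratinocytes. Each comparison is given as TiO2 minus untreated, or as smaller minus larger particle, on the log2 scale with SE from limma.

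For T-7, the smallest particle, 5 genes fell, and 3 of them belong to the ID family. ID2 fell by 2.56 on the log2 scale (SE 0.22, 5.9-fold, adjusted p = 0.0092), ID3 by 1.86 (SE 0.14, 3.62-fold, adjusted p = 0.0042) and ID1 by 1.62 (SE 0.18, 3.06-fold, adjusted p = 0.046). These genes encode inhibitors of DNA binding, dominant-negative partners of basic helix-loop-helix transcription factors and known targets of bone morphogenetic protein (BMP) signalling. DLX2, a homeobox transcription factor, fell by 1.16 (SE 0.08, adjusted p = 0.0042) and ZNF114, a zinc finger protein, by 1.34 (SE 0.15, adjusted p = 0.046). All 5 were lower at each of the 3 times. ID2 stood at -1.77, -3.04 and -2.87 at 2, 6 and 24 h, ID3 at -1.60, -1.71 and -2.27, and DLX2 at -1.07, -1.23 and -1.17. The fourth family member, ID4, was at -2.77 (SE 0.32) with an adjusted p of 0.056. The inhibitory SMAD gene SMAD6, another BMP target, was at -1.39 (SE 0.25, adjusted p = 0.31). The values of ID4 and SMAD6, which did not pass, were chosen here after they were seen.

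The 5 were the only genes called for T-7 among 18646 in limma, 0 higher and 5 lower, while 2913 had an unadjusted p under 0.05 (2169 higher, 744 lower) where chance gives 932. Of 41078 probes, 13 were called, 2 higher and 11 lower (26 after the 75th percentile shift, 1 and 25, and 5 after quantile normalization, 2 and 3), with 6237 at an unadjusted p under 0.05. They included both probes of ID2 (-2.50 and -2.62), and single probes of ABCA1, the cholesterol efflux transporter (-0.97, SE 0.11), and of KMO, kynurenine 3-monooxygenase (1.71, SE 0.14). Quantile normalization called 2 genes higher and 3 lower and ended the calls of ID1 and DLX2. No gene was called when the 6 h columns, the 24 h columns, the 6 h control column or the 6 h T-7 column was left out, or when the variance trend was fitted, and 1 was called without the 2 h columns. With only the columns compared 0 genes and 0 probes were called. In the fixed panel no gene passed: the early growth response gene EGR1 was at 0.79 (SE 0.15), the cytokine gene TNF at 0.56 (SE 0.11), IVL, which encodes the cornified envelope protein involucrin, at -0.64 and the gelatinase gene MMP9 at 0.99 (SE 0.48).

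**Figure D1:**
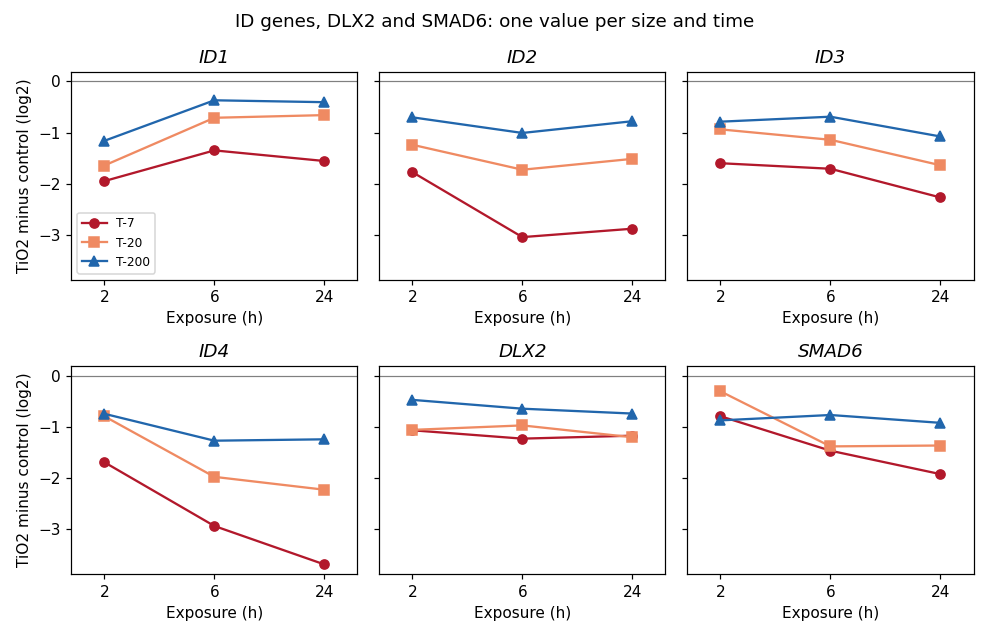
Log2 difference of TiO2 minus the untreated column of the same time (y axis) against exposure in hours (x axis) for ID1, ID2, ID3, ID4, DLX2 and SMAD6, with 1 line per particle size and 1 column per point, so no error bars. All points lie below 0, from -0.31 for SMAD6 with T-20 at 2 h to -3.68 for ID4 with T-7 at 24 h.

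Among the gene lists, 7 of 42 were called for T-7, and 0 with an estimated correlation or with directional fry. Exchanging T-7 and control columns within times called as many lists or more in all 4 cases, the real one included (up to 13). Targets of NRF2, the regulator of the antioxidant response, were lower for 25 of 27 members (median -0.13, adjusted p = 4.6e-07, and 0.67 as the adjusted p with an estimated correlation). The largest were AKR1B10, an aldo-keto reductase, at -0.75, the cystine transporter SLC7A11 at -0.58, GCLC, which makes the first step of glutathione synthesis, at -0.51 and the quinone reductase NQO1 at -0.35. Heat shock and chaperone genes were lower for 20 of 23 (median -0.18, adjusted p = 1.1e-05, and adjusted p = 0.67 with an estimated correlation), with HSPA4L at -0.42 and HSPB8 at -0.41 against CRYAB at 0.39. Genes of G2/M and mitosis were lower for 39 of 44 (median -0.11, adjusted p = 4.6e-07, and adjusted p = 0.95 with an estimated correlation), among them the spindle checkpoint gene MAD2L1 (-0.37), TOP2A (-0.32) and AURKA (-0.29). Proteasome genes were lower for 25 of 30 (median -0.10, adjusted p = 3.1e-05) and ribosome biogenesis genes for 28 of 37 (median -0.08, adjusted p = 5.1e-05), each with an adjusted p of 0.95 with an estimated correlation. NRF2 and heat shock medians were negative at every time, while G2/M, ribosome biogenesis and proteasome lists leaned on 24 h. G2/M medians were -0.01, -0.01 and -0.40 at 2, 6 and 24 h and ribosome biogenesis medians -0.01, 0 and -0.29. Proteasome medians were -0.09, 0.10 and -0.27, with 20 of 30 proteasome genes higher at 6 h. Solute transporters were lower for 19 of 28 (median -0.05, adjusted p = 0.0079, and adjusted p = 0.67 with an estimated correlation). Over all genes, and also adjusted over the list alone, 0 members of these lists passed in limma. All 7 lists kept their call after quantile normalization.

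The remaining called list for T-7 was the fibroblast markers, higher for 13 of 15 (median 0.38, adjusted p = 0.0079, and adjusted p = 0.95 with an estimated correlation), with COL1A2 at 0.63 and COL6A3 at 0.54, and 0 members passing over all genes or adjusted over the list alone. The markers of other cell types lay on the same side without a call. Medians were 0.26 for melanocyte (adjusted p = 0.60), 0.23 for leukocyte (adjusted p = 0.062), 0.25 for endothelial (adjusted p = 0.29) and 0.17 for simple epithelium markers (adjusted p = 0.78). Probes with no gene symbol had a median of 0.30 for T-7 at 24 h and named genes 0.08. TGF-beta targets went both ways, 17 higher and 12 lower, with 2 members (ID1 and ID3) called over all genes and 8 adjusted over the list alone, and were not called as a list (adjusted p = 0.62). Extracellular matrix components had a median of 0.14 (33 of 42 higher, adjusted p = 0.41), matrix proteases and inhibitors 0.12 (22 of 32, adjusted p = 0.64) and integrins and focal adhesion genes 0.09 (29 of 37, adjusted p = 0.32), so none of these groups was called against the control.

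For T-20, 1 gene fell past the threshold. DLX2 fell by 1.08 (SE 0.08, 2.11-fold, adjusted p = 0.013), with -1.06, -0.97 and -1.20 at 2, 6 and 24 h. The other genes of largest change did not pass. ID4 was at -1.67 (adjusted p = 0.69), ID2 at -1.49 (adjusted p = 0.31), ID3 at -1.24 (SE 0.14, adjusted p = 0.092) and ZNF114 at -1.06 (adjusted p = 0.27). On the higher side stood SLC45A2, a transporter of pigment cells, at 1.22 (SE 0.14, adjusted p = 0.092), then CETN1 at 1.27, LINC02476 at 1.20, EMX2 at 1.18 and KIAA0754 at 1.17, each with an adjusted p of 0.80. In limma 0 of 41078 probes were called (1833 at an unadjusted p under 0.05), and of the genes 944 had an unadjusted p under 0.05 where chance gives 932. The call of DLX2 ended with the variance trend first planned, with only the columns compared, without the columns of any 1 time and without any 1 control column, each of which left 0 genes.

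Of the lists, 13 were called for T-20 and 0 with an estimated correlation (lowest adjusted p = 0.82) or with directional fry. Cholesterol synthesis genes were higher for 20 of 21 (median 0.23, adjusted p = 0.00025, and adjusted p = 0.82 with an estimated correlation), led by INSIG1, a sterol-sensing regulator, at 0.56 and HMGCS1, the first committed synthase of the pathway, at 0.51. This average was carried by 24 h: the medians were 0.09, -0.03 and 0.79 at 2, 6 and 24 h, with 14 of 21 lower at 6 h. TGF-beta targets were lower for 20 of 29 (median -0.07, adjusted p = 3.4e-05, and adjusted p = 0.82 with an estimated correlation), with 0 members called over all genes and 5 adjusted over the list alone. Their lowest members were the BMP-responsive ID3 (-1.24), ID1, SMAD6 (-1.02) and SMAD7 (-0.69). Without ID1 and ID3, a test chosen after the result was seen, the list stayed called (adjusted p = 0.0017, and 0.82 with an estimated correlation). Interferon response genes were higher for 35 of 37 (median 0.09, adjusted p = 0.016) and cytokine genes for 28 of 36 (median 0.16, adjusted p = 0.046), with TNF at 0.54 and the chemokine CCL2 at 0.52. Interferon medians were 0.19, -0.05 and 0.18 at the 3 times and cytokine medians -0.07, 0.22 and 0.24, so each list had 1 time on the other side. After a shift to a common 75th percentile, which moves the median of all genes for T-20 to -0.16, those medians became -0.11 and -0.03 and that of the fibroblast markers (0.18 as deposited, 12 of 15 higher, adjusted p = 0.033) -0.01. Beside that move of all genes the interferon call ended (adjusted p = 0.22) while the cytokine and fibroblast calls stayed (adjusted p = 0.003 and 0.012). Quantile normalization kept the interferon call (adjusted p = 9.9e-05) and ended the other pair (adjusted p = 0.13 and 0.19). Proteasome (25 of 30), ribosome biogenesis (30 of 37) and G2/M genes (35 of 44) were lower in the average over times, with medians of -0.06, -0.07 and -0.06. These too came from late times: G2/M genes had medians of 0.02, 0.03 and -0.27, with 32 of 44 higher at 6 h, proteasome genes -0.01, -0.01 and -0.20 and ribosome biogenesis genes 0.02, -0.08 and -0.17. TGF-beta medians were -0.10, -0.14 and 0.01. NRF2 targets, G1/S, oxidative phosphorylation, cytosolic ribosomal protein and aryl hydrocarbon receptor with xenobiotic enzyme lists were also called lower, with medians between -0.07 and -0.02 and each with a median above 0 at 1 time or more. With quantile normalization cholesterol synthesis (adjusted p = 0.034), TGF-beta targets (0.032), proteasome (0.0076) and ribosome biogenesis genes (8.4e-06) stayed called, and G2/M (0.52), G1/S (0.52), NRF2 (0.42), oxidative phosphorylation (0.31), cytosolic ribosomal protein (0.13) and receptor with xenobiotic enzyme lists (0.32) did not. Only 2 lists were called without the 24 h columns.

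For T-200, the largest particle, no gene passed: in limma 0 of 18646 genes and 0 of 41078 probes were called, with 1114 genes and 2263 probes at an unadjusted p under 0.05. LPL, lipoprotein lipase, was highest at 1.32 (SE 0.21, adjusted p = 0.53; 1.36, 1.36 and 1.23 at the 3 times), followed by POU4F1 at 1.30, KNCN at 1.19, NELL2 at 1.14 and KIAA0754 at 1.11. On the lower side were ID4 at -1.09, ID3 at -0.85 (adjusted p = 0.53), SMAD6 at -0.86, LHX2 at -0.84 and ID2 at -0.83 (adjusted p = 0.79), and outside the 5 largest DLX2 at -0.62 and ID1 at -0.65.

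Lists called for T-200 numbered 8, and 0 with an estimated correlation (lowest adjusted p = 0.44) or with directional fry. Interferon response genes were higher for 33 of 37 (median 0.09, adjusted p = 0.00016, and adjusted p = 0.88 with an estimated correlation), with the chemokines CXCL10 at 0.58 and CXCL11 at 0.56 and the interferon-induced IFI44L at 0.52. After the 75th percentile shift, which moves the median of all genes to -0.12, their median was -0.05 and the call stayed (adjusted p = 0.00056, and 4.3e-08 after quantile normalization). Cytokine genes were higher for 29 of 36 (median 0.19, adjusted p = 0.0079), with CXCL8 at 0.59 and 2 members passing adjusted over the list alone, and cholesterol synthesis genes for 18 of 21 (median 0.26, adjusted p = 0.0079). The cholesterol average was carried by 24 h, with medians of -0.06, -0.05 and 0.78 at 2, 6 and 24 h and 19 of 21 lower at 6 h. The cytokine medians were -0.01, 0.38 and 0.17. G1/S genes were lower for 36 of 45 (median -0.07, adjusted p = 0.00016, CCNE2 at -0.40) and G2/M genes for 36 of 44 (median -0.08, adjusted p = 0.0014). A list of aryl hydrocarbon receptor targets together with other xenobiotic enzymes was lower for 16 of 21 (median -0.09, adjusted p = 0.0014, and adjusted p = 0.44 with an estimated correlation), led by AHRR, the repressor of that receptor, at -0.51. TGF-beta targets (median -0.03) and proteasome genes (median -0.05) each had an adjusted p of 0.045, the former 0.21 without ID1 and ID3. Quantile normalization ended the calls of G1/S (adjusted p = 0.073), G2/M (0.17), cytokine (0.074), cholesterol synthesis (0.12), receptor with xenobiotic enzyme (0.074), TGF-beta (0.48) and proteasome lists (0.12). Without the 2 h columns, or without those of 24 h, 5 lists were called.

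The mean of the 3 sizes asked for the average change with TiO2, which 1 size can carry. DLX2 fell by 0.95 (SE 0.07, adjusted p = 0.0071) and ID3 by 1.31 (SE 0.11, adjusted p = 0.013), the 2 genes called, both lower. Those that did not pass included ID4 at -1.84 (adjusted p = 0.23), ID2 at -1.63 (adjusted p = 0.068), ID1 at -1.09 (adjusted p = 0.20) and SMAD6 at -1.09 (adjusted p = 0.50). The largest positive values were PTPRD at 1.29, KIAA0754 at 0.94, SEPTIN5 at 0.92 and CHRM4 and FOXI1 at 0.91, each with an adjusted p of 0.50. EGR1 (0.73, adjusted p = 0.44) and TNF (0.49, adjusted p = 0.47) were positive in all 9 TiO2 columns. Of 18646 genes 1769 had an unadjusted p under 0.05 in limma, and 7 of 41078 probes were called, 1 higher and 6 lower. With quantile normalization 2 genes were called higher and 4 lower, and 0 genes were called without the 6 h or the 24 h columns, or without the 2 h or the 6 h control column. With the variance trend, the setting first planned, 0 genes and 1 probe were called, and 0 genes with robust moderation added.

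For this mean 13 lists were called (as many or more in 14 of 64 exchanges of the control within times) and 0 with an estimated correlation (lowest adjusted p = 0.66) or with directional fry. G2/M genes (38 of 44 lower, median -0.08, adjusted p = 3.2e-06), proteasome genes (26 of 30 lower, adjusted p = 5.4e-05) and NRF2 targets (22 of 27 lower, adjusted p = 0.00014) were called most strongly, with an adjusted p of 0.86 with an estimated correlation for each. Quantile normalization ended the calls of G2/M genes and NRF2 targets (adjusted p = 0.13 for each) and kept that of the proteasome (adjusted p = 0.0029). It also kept ribosome biogenesis genes (29 of 37 lower, median -0.07, adjusted p = 0.0011, and 0.00011 after it), called under all 4 scalings, and interferon response genes (30 of 37 higher, median 0.08, adjusted p = 0.04, and 4e-05 after it). After the 75th percentile shift the interferon median was -0.12 and the call ended (adjusted p = 0.39), and with median centring it ended too (0.059). Both lists had an adjusted p of 0.86 with an estimated correlation. G1/S (adjusted p = 0.0011), receptor with xenobiotic enzyme (0.003), heat shock (0.04) and solute transporter lists (0.04) were also called lower, and quantile normalization ended these calls (0.22, 0.13, 0.62 and 0.13). At 2, 6 and 24 h the medians were -0.01, 0.02 and -0.29 for G2/M genes, -0.05, 0.01 and -0.17 for proteasome genes and -0.02, -0.06 and -0.12 for NRF2 targets. Cholesterol synthesis genes were higher for 20 of 21 (median 0.20, adjusted p = 0.018, and adjusted p = 0.91 with an estimated correlation), but their median was about 0 (-0.002) after the 75th percentile shift, which moves the median of all genes to -0.17. The average came from 24 h alone: medians were -0.03 at 2 h (14 of 21 lower), 0 at 6 h (11 of 21 lower) and 0.66 at 24 h. Relative to all genes they stayed called after that shift (adjusted p = 0.0086), and quantile normalization ended the call (adjusted p = 0.21). Fibroblast and leukocyte markers were each higher for 13 of 15 (medians 0.24 and 0.20, adjusted p = 0.022 and 0.037, and adjusted p = 0.86 with an estimated correlation). After the same shift the leukocyte median was -0.01 (adjusted p = 0.053, and fibroblast markers 0.0073), and quantile normalization ended both calls (adjusted p = 0.13 for fibroblast and 0.42 for leukocyte markers). TGF-beta targets were split, 14 higher and 15 lower, with 1 member called over all genes and 5 adjusted over the list alone (median -0.02, adjusted p = 0.021, and 0.42 after quantile normalization). Without ID1 and ID3 their median was 0.02 and the call ended (adjusted p = 0.24).

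**Figure D2:**
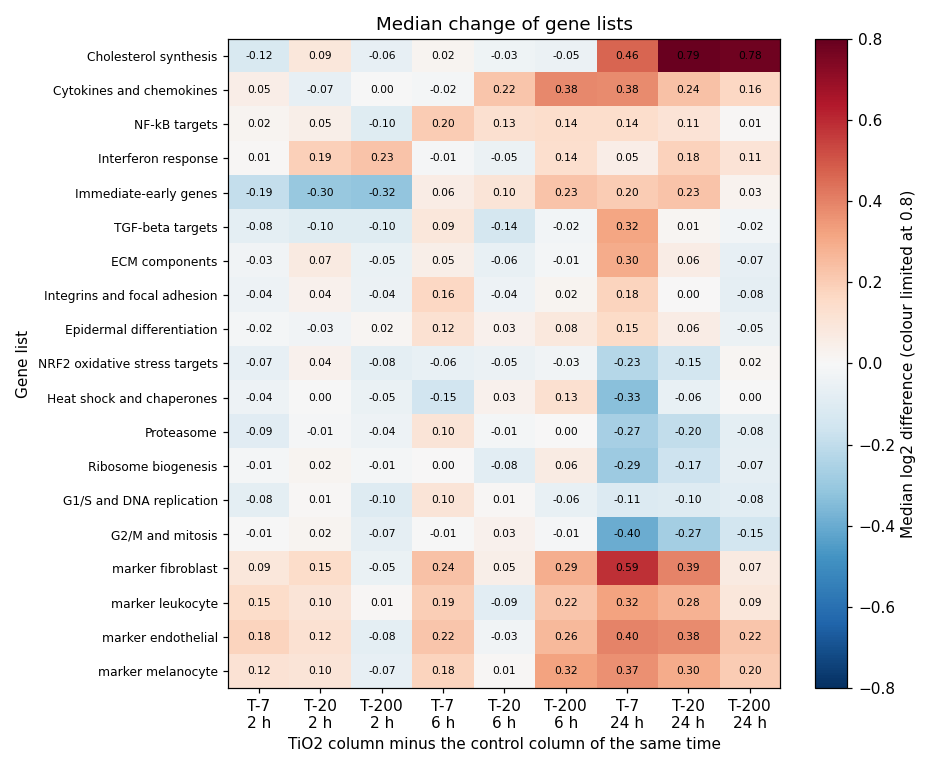
Median log2 difference of TiO2 minus the untreated column (colour, limited at 0.8 either way) of 19 gene lists (y axis) in each of the 9 TiO2 columns (x axis, particle size within exposure time), with 1 column per cell and no error. At 24 h the medians of cholesterol synthesis genes were 0.46, 0.79 and 0.78 and those of G2/M genes -0.40, -0.27 and -0.15 for T-7, T-20 and T-200; a shift to a common 75th percentile moves all genes down (medians of -0.16 for T-20 and -0.12 for T-200) and with them turns the small positive interferon medians of the averages over time negative, while the interferon list of T-200 stays called (adjusted p = 0.00056).

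Particles of different size were then compared directly, which does not use the control columns. No gene differed past the threshold: limma called 0 of 18646 genes for T-7 minus T-200 (2196 at an unadjusted p under 0.05, where chance gives 932), for T-7 minus T-20 (535) and for T-20 minus T-200 (808). For T-7 minus T-200, ID2 was at -1.73 (95% interval -2.23 to -1.24, adjusted p = 0.35), with -1.07, -2.03 and -2.10 at 2, 6 and 24 h. ID4 was at -1.68 (-2.42 to -0.95, adjusted p = 0.38), ID3 at -1.01 (-1.32 to -0.69, adjusted p = 0.35), ID1 at -0.97 (-1.38 to -0.56) and DLX2 at -0.54 (-0.73 to -0.34). NELL2 (-1.40) and KRT24 (-1.24) also ranked low, and SLC9C1 (1.48), the pro-apoptotic gene BMF (1.36), DPPA3 (1.29), DEFB127 (1.16) and PRAMEF2 (1.10) high, none passing. For T-7 minus T-20, SLC45A2 was at -1.38 (-1.70 to -1.06, adjusted p = 0.11) and ID2 at -1.07 (-1.57 to -0.57). For T-20 minus T-200, NELL2 was at -1.36 and CYP4Z1 at -1.26, with an adjusted p of 0.95.

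Matrix and adhesion lists were among those called in the comparison of the smallest with the largest particle. Exchanging columns of these sizes within times called as many lists or more in all 4 cases, the real one included (up to 16 against 11). Integrins and focal adhesion genes were higher with T-7 than with T-200 for 30 of 37 (median 0.17, adjusted p = 0.014, and adjusted p = 0.90 with an estimated correlation), with the integrins ITGB6 at 0.49 and ITGB4 at 0.34 and the syndecan SDC4 at 0.33. Matrix proteases and inhibitors were higher for 25 of 32 (median 0.13, adjusted p = 0.037, and 0.90 with an estimated correlation), with MMP9 at 1.03 (-0.06 to 2.12) and the collagenase MMP13 at 0.55. Matrix components were higher for 32 of 42 (median 0.17, adjusted p = 0.041, 0.90 with an estimated correlation and 0.089 after quantile normalization), with fibronectin, FN1, at 0.45 (-0.07 to 0.97), the anchoring fibril collagen COL7A1 at 0.42 and BGN at 0.39 against VCAN at -0.41. Fibroblast markers, which include collagens, lay on the same side (14 of 15 higher, median 0.16, adjusted p = 0.041, 0.90 with an estimated correlation and 0.15 after quantile normalization). Heat shock genes were lower for 20 of 23 (median -0.20, adjusted p = 8.8e-06, and 0.90 with an estimated correlation), with HSPA1L at -0.82, CHORDC1 at -0.63 and HSPH1 at -0.49. Interferon response genes were lower for 31 of 37 (median -0.13, adjusted p = 6.7e-05), with IFI44L at -0.60, and NRF2 targets for 20 of 27 (adjusted p = 0.00028), each with an adjusted p of 0.90 with an estimated correlation. Ribosome biogenesis (27 of 37 lower), G2/M, histone and proteasome genes were the other called lists of 11, and quantile normalization ended the calls of G2/M (adjusted p = 0.34) and proteasome genes (0.091). All 11 had an adjusted p of 0.90 with an estimated correlation, 0 were called by directional fry, and over all genes 0 members passed. These averages were uneven over the times. At 2, 6 and 24 h the medians were 0.05, 0.06 and 0.26 for integrins, 0.05, 0.04 and 0.36 for matrix proteases, 0.04, 0.02 and 0.32 for matrix components, 0.22, -0.04 and 0.35 for fibroblast markers and -0.01, -0.05 and -0.22 for NRF2 targets. They were -0.03, -0.26 and -0.32 for heat shock genes, -0.21, -0.19 and -0.03 for interferon genes and 0, -0.03 and -0.23 for ribosome biogenesis. They changed sign between times for G2/M (0.08, 0.02 and -0.22), histone (-0.31, 0.09 and -0.03) and proteasome genes (-0.04, 0.11 and -0.19). Adjusted over the list alone 4 heat shock members and 0 matrix components passed, and 6 lists were called without the 24 h columns.

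Between T-7 and T-20 10 lists were called. Exchanging columns within times called as many or more in 3 of 4 cases, the real one included (up to 11). Heat shock genes (20 of 23, median -0.15, adjusted p = 6e-07), NRF2 targets (24 of 27, median -0.10, adjusted p = 4.8e-06) and solute transporters (median -0.06, adjusted p = 0.012, and 0.057 after quantile normalization) were lower with T-7, with an adjusted p of 0.80 with an estimated correlation. Cholesterol synthesis genes were lower for 19 of 21 (median -0.18, adjusted p = 0.00034, and adjusted p = 0.99 with an estimated correlation). Integrins and focal adhesion genes (32 of 37, median 0.10, adjusted p = 8e-04), TGF-beta targets (22 of 29, median 0.17, adjusted p = 0.0022; 2 members adjusted over the list alone, 0 over all genes) and YAP and serum response targets (22 of 27, median 0.08, adjusted p = 0.0022) were higher, with an adjusted p of 0.92 with an estimated correlation. At 2 h the medians of these 3 lists had the other sign (-0.08, -0.09 and -0.004), and cholesterol synthesis had 0.04 at 6 h against -0.21 and -0.31 at 2 and 24 h. Among TGF-beta targets ZEB1 was at 0.69 and INHBA at 0.66 while ID3 and ID1 were at -0.62 and -0.61. Without that pair the list had an adjusted p of 1.9e-05, and of 0.86 with an estimated correlation. Cytosolic ribosomal proteins were higher for 38 of 44 (median 0.06, adjusted p = 0.031, and 0.99 with an estimated correlation) but had a median of -0.01 after the 75th percentile shift, which ended the call (adjusted p = 0.34). Quantile normalization kept it (adjusted p = 0.0049). It rested on 6 h, with medians of -0.10, 0.26 and -0.01. Interferon response genes (31 of 37, median -0.07, adjusted p = 0.00034, and 0.92 with an estimated correlation) and G2/M genes (37 of 44, median -0.06, adjusted p = 8e-04, and 0.99 with an estimated correlation) were lower with T-7. The first had 0.02 at 6 h against -0.15 and -0.11 at 2 and 24 h. Between T-20 and T-200 5 lists were called (as many or more in 2 of 4 cases), with cytosolic ribosomal proteins lower for 40 of 44 (median -0.08, adjusted p = 9.3e-06), ribosome biogenesis genes for 29 of 37 (adjusted p = 0.0012) and YAP targets for 19 of 27 (adjusted p = 0.017, ANKRD1 at -0.64). TGF-beta targets (20 of 29 lower, adjusted p = 0.031, and 0.088 without ID1 and ID3) and oxidative phosphorylation genes (25 of 39 lower, adjusted p = 0.041, and 0.16 after quantile normalization) were the others. The ribosomal proteins were lower at every time, ribosome biogenesis had a median of 0.04 at 2 h and YAP targets one of 0.04 at 24 h. Each of these 5 had an adjusted p of 0.91 with an estimated correlation, and directional fry called 0 lists in either comparison.

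With the 3 sizes taken as repeats within each time, the time with most calls depended on the scaling. It was 24 h as deposited (34, against 9 at 2 h) and with median centring (46 against 15), and 2 h with quantile normalization (264, against 220 at 24 h) and after the 75th percentile shift (96 against 42). That model has 1 untreated column per time, assumed to vary like the sizes, so an error of that column enters every call unmeasured. At 24 h 29 genes were called higher and 5 lower (2247 at an unadjusted p under 0.05), against 0 and 9 at 2 h (997) and 0 and 1 at 6 h (454). With the T-7 column of 24 h set apart in place of the untreated column 34 genes were called, as many as with the untreated column. T-20 set apart there gave 3 and T-200 0. At 2 h T-7, T-20 and T-200 set apart gave 14, 5 and 2, and at 6 h 7, 0 and 32. At each time at least 1 TiO2 column thus gave as many calls as the untreated one. Those called higher at 24 h included APOC2, an apolipoprotein that activates lipoprotein lipase (2.96, SE 0.36, adjusted p = 0.030), NLRP3, the inflammasome sensor (2.79, SE 0.28, adjusted p = 0.021), MEFV, which encodes pyrin (2.05, SE 0.26), and CTSG, a granule protease (2.05, SE 0.23). The lipoxygenases ALOX12B (1.41, SE 0.18, adjusted p = 0.035), which acts in the epidermal barrier, and ALOX12 (1.16, SE 0.16) were among them, as was LSS, lanosterol synthase of the cholesterol pathway (1.05, SE 0.14, adjusted p = 0.035). Calls as large were HSPA12A-AS1 (2.71), GRK1 (2.60), OR2A25 (2.09) and GPR142 (1.95). The genes described were picked from the 29, and no theme among them was tested. At 2 h the glutathione transferase gene GSTA1 was at -2.99 (SE 0.19, adjusted p = 0.0018; the untreated column itself at -0.71), FGG, the fibrinogen gamma chain, at -1.89 (SE 0.16; untreated 0.47) and RECK, a membrane inhibitor of matrix proteases, at -1.24. Some calls came from the untreated column. LINC01093 was at 3.21 in the control of 24 h, ZNF660 at 2.64 and MYOCD-AS1 at 2.65 in the control of 2 h, and DPP4, the 1 gene called at 6 h, at 2.79 in the control of 6 h. Leaving out the columns of T-7 left 0 genes at every time, and leaving out any 1 size left at most 2 at 2 h, 0 at 6 h and 1 at 24 h. The split was 70 higher and 194 lower at 2 h, 5 and 115 at 6 h and 81 and 139 at 24 h with quantile normalization, and 10 and 86, 0 and 3, and 23 and 19 after the 75th percentile shift, so that quantile normalization turned the balance at 24 h from higher to lower. Quantile normalization gives the narrower control columns the spread of the TiO2 columns, and its part in these counts was not tested. The 75th percentile shift moves the median of all genes at those times to -0.16, -0.11 and -0.23. With median centring it was 4 and 11 at 2 h and 35 and 11 at 24 h.

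Cholesterol synthesis was the group of largest change at 24 h. All sizes were set against the same untreated column there, whose own error enters every value of this paragraph. Of its 21 members 20 were higher (median 0.66, adjusted p = 6.9e-13, and adjusted p = 0.72 with an estimated correlation), 1 was called over all genes and 16 adjusted over the list alone. HMGCS1 stood at 1.06, 1.61 and 1.54 and INSIG1 at 1.03, 1.56 and 1.44 for T-7, T-20 and T-200. HMGCS1 at 24 h (1.40, SE 0.21) had an adjusted p of 0.052. G2/M genes were lower for 40 of 44 (median -0.29, adjusted p = 6.9e-13, and adjusted p = 0.72 with an estimated correlation), proteasome genes for 27 of 30 (median -0.17, adjusted p = 1.1e-06) and ribosome biogenesis genes for 32 of 37 (median -0.19, adjusted p = 9.7e-05), the last pair with an adjusted p of 0.88 with an estimated correlation. Fibroblast markers were higher for 14 of 15 (median 0.34, adjusted p = 0.029, and adjusted p = 0.88 with an estimated correlation). Markers of endothelium (9 of 10 higher, median 0.30), melanocytes (7 of 10, 0.28) and leukocytes (13 of 15, 0.25) lay on the same side without a call. Probes with no symbol had medians of 0.30, 0.29 and 0.13 for T-7, T-20 and T-200. Also called lower at 24 h were G1/S (adjusted p = 0.00063), NRF2 (0.0048), oxidative phosphorylation (0.015) and heat shock lists (0.029), each 0.88 with an estimated correlation. So were receptor with xenobiotic enzyme (0.029) and endocytosis lists (0.049), each 0.72. IVL was at -1.21, -1.35 and -1.04 for the 3 sizes (mean -1.20, SE 0.18, adjusted p = 0.051). At 2 h immediate-early genes were lower for 33 of 41 (median -0.28, adjusted p = 6.3e-09, and adjusted p = 0.93 with an estimated correlation), with EGR3 at -0.74, -1.98 and -0.92 and FOSB at -0.60, -0.76 and -0.71, while EGR1 was positive. That list holds ID1 (-1.95, -1.64 and -1.16), ID2 (-1.77, -1.24 and -0.70) and ID3 (-1.60, -0.94 and -0.79). Without these 3 it stayed called at 2 h (30 of 38 lower, median -0.27, adjusted p = 3.6e-07, and 0.93 with an estimated correlation). TGF-beta targets were also lower at 2 h (20 of 29, median -0.06, adjusted p = 0.0059, and 0.93 with an estimated correlation), a call that ended without ID1 and ID3 (adjusted p = 0.051). At 6 h NF-kB targets (21 of 24, median 0.16, adjusted p = 0.019) and immediate-early genes (33 of 41, median 0.14, adjusted p = 0.025) were higher, each with an adjusted p of 0.96 with an estimated correlation and 1 member passing adjusted over the list alone. The first had a median of -0.01 after quantile normalization and the second of -0.01 after the 75th percentile shift. Without the 3 ID genes immediate-early genes had an adjusted p of 0.0013 at 6 h, of 0.041 at 24 h (0.23 with them) and of 8.8e-08 for the difference of 24 h from 2 h. With an estimated correlation these were 0.96, 0.87 and 0.93. Cytokine genes were also higher at 6 h (26 of 36, median 0.19, adjusted p = 0.025), and solute transporters (20 of 28, median -0.08, adjusted p = 0.025) and NRF2 targets (19 of 27, median -0.06, adjusted p = 0.042) were lower, each with an adjusted p of 0.96 with an estimated correlation. The difference of 24 h from 2 h was called for cholesterol synthesis (median 0.67, adjusted p = 4.8e-16), G2/M (median -0.25, adjusted p = 3.1e-08), immediate-early (median 0.35, adjusted p = 5.7e-07), ribosome biogenesis (median -0.17, adjusted p = 0.0078) and proteasome genes (median -0.11, adjusted p = 0.011), each with an adjusted p of 0.93 with an estimated correlation.

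**Figure D3:**
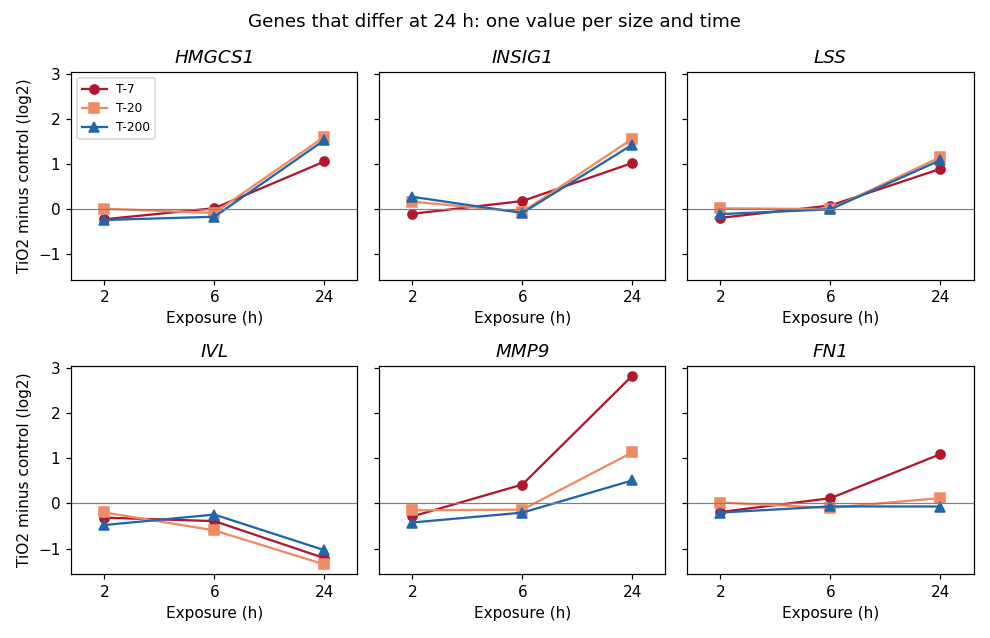
Log2 difference of TiO2 minus the untreated column of the same time (y axis) against exposure in hours (x axis) for HMGCS1, INSIG1, LSS, IVL, MMP9 and FN1, with 1 line per particle size and 1 column per point, so no error bars. The 3 sterol genes are highest at 24 h with each size, IVL lies between -1.04 and -1.35 there, and MMP9 (2.84) and FN1 (1.10) are highest with T-7.

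Single columns gave the size of each response without a test. The number of genes at 2-fold or more from the control at 24 h was 742 for T-7 (646 higher, 96 lower), 602 for T-20 (540 and 62) and 368 for T-200 (308 and 60). Between TiO2 columns of 24 h the same count was 283 for T-7 and T-20, 481 for T-7 and T-200 and 287 for T-20 and T-200. At 2 h the counts were 347, 487 and 346 for T-7, T-20 and T-200, against 247 to 270 between TiO2 columns. At 6 h they were 286, 193 and 314, against 283 to 393 between TiO2 columns, so that as a set the 6 h columns, as deposited, lay no farther from the control than from each other. These counts depend on scaling: quantile normalization gave 383 in place of 193 for T-20 at 6 h and 454 in place of 742 for T-7 at 24 h. MMP9 at 24 h was at 2.84 with T-7, 1.14 with T-20 and 0.51 with T-200, MMP10, stromelysin 2, at 1.72, 0.62 and -0.46, and FN1 at 1.10, 0.12 and -0.07. TXNRD1, thioredoxin reductase and an NRF2 target, was at -0.77, -0.41 and -0.18, and the mitotic cyclin CCNB1 at -0.54, -0.37 and -0.16. Matrix components had medians of 0.30, 0.06 and -0.07 at 24 h. By the size rule T-7 at 24 h also named SLC9C1 (2.66), RHOBTB3 (-1.79), the leukotriene hydroxylase CYP4F3 (-1.75) and the Notch target HES5 (-1.74), and HES5 was at -1.52 with T-20 and -1.08 with T-200. Among the less variable genes, from which single columns were named, T-7 at 2 h was led by RBPMS2 (3.21) and LDLRAD1 (-2.79), T-20 at 2 h by CETN1 (2.10) and LDLRAD1 (-2.92), and T-200 at 2 h by TREML4 (4.05) and FGG (-1.97). At 6 h the extremes among these genes were MPG (1.99) and ID2 (-3.04) for T-7, C16orf82 (1.94) and ID2 (-1.72) for T-20, and ROPN1B (2.38) and RNF213-AS1 (-1.31) for T-200.

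Whether the untreated column lay apart from the TiO2 columns depended on the measure. The mean SD of log2 differences from control to TiO2 exceeded that among TiO2 columns by 0.015 (exact one-sided permutation p = 0.281 over 64 choices, of which the smallest possible p is 0.0156). By time the excess was 0.001, -0.04 and 0.08 at 2, 6 and 24 h, so that the control lay farther away at 24 h and nearer at 6 h. The median absolute difference gave an exact permutation p of 0.469, with -0.04, -0.03 and 0.07 at the 3 times. By 1 minus Pearson's correlation the control did lie apart, with an excess of 0.267 and the smallest possible exact permutation p, 0.0156 (0.22, 0.13 and 0.45 at the 3 times). That measure alone of these 3 depends on what was subtracted from all columns of a time. With each probe centred on the 4 columns of its time, a test chosen after that result was seen, it gave 0.03 and an exact permutation p of 0.312. A single time has too few choices for a test.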

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

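The test of the difference between times in this part was chosen before the result was seen, the exchange of the untreated column for a TiO2 column only after it, and the comparison of signs for the last genes is a description without a test. The TiO2 effect at 24 h differed from that at 2 h for 6 genes in limma, 4 with a positive and 2 with a negative difference, and 993 had an unadjusted p under 0.05. The test rests on 1 untreated column at each time, and the SD over sizes that share it leaves out its error. With the T-7 column of 2 h set apart in place of the untreated column 88 genes were called, so these calls do not exceed what a TiO2 column can give. GSTA1 differed by 3.43 (mean TiO2 minus control -2.99 ± 0.22 at 2 h and 0.44 ± 0.14 at 24 h, SD over the 3 sizes, adjusted p = 0.0065), with -0.71 in the untreated column of 2 h itself. FGG differed by 2.00 (-1.89 ± 0.07 and 0.11 ± 0.15, adjusted p = 0.045) and XKR4 by 1.69 (-1.20 ± 0.04 and 0.48 ± 0.10, adjusted p = 0.043), with 0.47 and 0.56 in that column. LGALS2, a galectin, differed by -1.66 (0.91 ± 0.09 and -0.74 ± 0.07, adjusted p = 0.020), with 0.06 in the untreated column of 2 h and -0.16 in that of 24 h. ZNF660 differed by 2.76 (-2.39 ± 0.06 and 0.36 ± 0.20, adjusted p = 0.0086), with 2.64 in the untreated column of 2 h itself. LINC01093 differed by -3.17 (0.03 ± 0.15 and -3.14 ± 0.19, adjusted p = 0.0065), with 3.21 in the untreated column of 24 h itself. Leaving out the columns of T-7, of T-20 or of T-200 left 0 of these calls, and quantile normalization gave 124 positive and 52 negative differences, median centring 5 and 2, and the 75th percentile shift, which moves the median difference of all genes to -0.11, 6 and 2.

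In the fixed panel 3 genes had one sign in every size at 2 h and the opposite sign in every size at 24 h, and the opposite signs themselves were not tested. DDIT3, the stress-response factor CHOP, went from 0.37 ± 0.17 at 2 h to -0.09 ± 0.02 at 24 h, a difference of -0.46 (SD, n = 3 sizes). CXCL1, a chemokine, went from 0.05 ± 0.03 to -0.08 ± 0.06, a difference of -0.13. MMP9 went from -0.29 ± 0.14 to 1.5 ± 1.2, a difference of 1.78. In limma these differences had adjusted p-values of 0.86, 1 and 0.99, so none passed.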

How the results depend on the processing

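Alternatives chosen only after the data were seen were the ratio against 0, leaving out noisy probes or the more variable genes, lists without ID1, ID2 and ID3, the correlation of centred probes, and the scalings applied to lists and to the counts within each time. Over the genes followed through the alternatives, 40 comparisons changed sign. None of these was of a gene called in the main fit, and none had values beyond the main SE on both sides of 0. The split of genes called at 24 h turned from 29 higher and 5 lower to 81 and 139 with quantile normalization, and the medians of some lists changed sign, as given with those lists. The counts moved, and except where the alternative used fewer columns or left out the control's own spread the cause was not tested. Over counts and distances, 291 comparisons with an alternative kept their side of the threshold or their size, 116 became weaker, 36 stronger and 29 moved. Over the genes followed, 2133 comparisons stayed the same, 98 became weaker, 47 stronger and 40 changed sign. Here the same means an unchanged sign and side of the threshold. Most genes followed were not called in the main fit, so for them it meant staying uncalled. Weaker means a lost call, which only the 5, 1 and 2 genes called for T-7, T-20 and the mean could have. The 98 are thus all losses of these few calls. No paired analysis was possible because the columns carry no replicate number, and exposure time was the block of the additive model. Dim filters and floors could not be run on values without a level, and differences between times were not run because the deposited ratios had removed them. The number of columns limits these tests, and what signal over background limits could not be judged without a level.

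Probes called for T-7 (13) were 0 with a variance trend, 0 with a trend and robust moderation, 7 without the time block, 0 with only the columns compared, 5 after quantile normalization and 26 after the 75th percentile shift. Those for the mean of the sizes (7) were 1, 0 and 2 under the first 3 of these, 11 after quantile normalization and 20 after the shift. T-200 gave 1 probe after the shift, and T-7 minus T-200 gave 1 without the block. Against 0, which leaves out the spread of the control columns, 5578, 21, 62 and 13296 probes were called for T-7, T-20, T-200 and their mean. The split of T-7 probes was 2 higher and 3 lower after quantile normalization, 2 and 12 after median centring and 1 and 25 after the shift.

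Genes called for T-7 (5) were 0 with either trend setting, 3 without the block, 0 with only the columns compared and 8 without noisy probes. T-20 (1) gave 0 with either trend setting, 0 with only the columns compared, 4 after quantile normalization (1 higher, 3 lower), 2 after the shift and 2 without noisy probes. T-200 gave 1 after quantile normalization, and T-7 minus T-20 gave 1 after the shift. The mean of the sizes (2) gave 0 with either trend setting, 1 without the block, 6 after quantile normalization and 7 after the shift. Against 0 the counts were 2655, 43, 3 and 6062.

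Lists called fell to 0 in all 7 comparisons with an estimated correlation and with fry. T-200 had 4 with the probe of highest mean per gene. After quantile normalization T-20 had 5, T-200 had 2 and the mean had 3. Without ID1, ID2 and ID3 the counts were 7, 13, 6 and 12 for T-7, T-20, T-200 and the mean, and 3 in place of 5 for T-20 minus T-200. Genes called within a time became 264 at 2 h, 120 at 6 h, 220 at 24 h and 176 for the difference after quantile normalization, 15 at 2 h with median centring, and 96 at 2 h and 3 at 6 h after the shift.

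Leaving out 1 time or 1 column gave 0 to 10 probes for T-7, 0 to 1 for T-20, 0 to 2 for the mean and 0 to 2 for T-7 minus T-200. For T-7, 0 probes were left without the 6 h columns, the 24 h columns, the control or T-7 column of 6 h, the T-7 column of 24 h or the T-200 column of 24 h, 1 without the control column of 24 h, and 10 without that of 2 h. It was 2 without the 2 h columns or the T-20 column of 2 or 24 h, 3 without the T-200 column of 2 h, 4 without the T-20 or T-200 column of 6 h and 5 without the T-7 column of 2 h. For the mean, 2 probes were left without the T-7 column of 2 h and 0 in every other case. Genes ranged from 0 to 7 for T-7, 0 to 2 for T-20, 0 to 3 for the mean, 0 to 2 for T-7 minus T-200 and 0 to 1 for T-7 minus T-20. For T-7, 7 genes were called without its own 2 h column, 0 without the 6 h columns, the 24 h columns, or the control or T-7 column of 6 h, 1 without the 2 h columns, 2 without its 24 h column, 2 without the control column of 24 h, and 3 without the T-20 column of 6 or 24 h or any 1 T-200 column. The call for T-20 ended without any 1 time, any 1 control column, the T-20 column of 2 or 24 h, or the T-7 or T-200 column of 24 h, and 2 genes were called without the T-7 column of 2 h or the T-200 column of 6 h. For the mean, 1 gene was left without the 2 h columns, the T-7 or T-20 column of 6 h or any 1 T-200 column, 0 without the 6 h or 24 h columns or the control column of 2 or 6 h, and 3 without the T-7 column of 2 h or the control column of 24 h. The genes for T-7 minus T-200 came without the T-7 column of 2 h (2) or the T-200 column of 24 h (1), that for T-7 minus T-20 without the T-200 column of 6 h. Probes for T-20 (1) and for T-7 minus T-200 (2) came without the T-7 column of 2 h. Lists ranged from 2 to 13 for T-20, 5 to 10 for T-200, 4 to 13 for the mean, 6 to 16 for T-7 minus T-200 and 3 to 6 for T-20 minus T-200, and the lowest for T-20, the mean and T-7 minus T-200 came without the 24 h columns, that for T-200 without the 2 h or the 24 h columns, and that for T-20 minus T-200 without the 6 h columns. Within a time, leaving out 1 size gave 0 to 2 genes at 2 h, 0 at 6 h, 0 to 1 at 24 h and 0 for the difference.

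Genes from the control at 1.5-fold or more numbered 1397, 1765 and 1377 at 2 h for T-7, T-20 and T-200, 1259, 833 and 1193 at 6 h and 2555, 2029 and 1353 at 24 h. At 3-fold they numbered 69, 94 and 51, then 49, 27 and 64, then 191, 159 and 60. Among the less variable genes at 2-fold they were 73, 67 and 55, then 38, 20 and 35, then 126, 96 and 43. Quantile normalization gave 383 for T-20 at 6 h and 454 for T-7 at 24 h. For the distance of the control column, 1 minus Pearson's correlation gave an exact permutation p of 0.0156 in place of 0.281. If the values are ratios to the control, as read here, TiO2 columns correlate through the control they share, and with each probe centred on the 4 columns of its time the exact permutation p was 0.312.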

Other observations

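The genes in the next paragraph, and the tests of a deviating control, of column shifts, of marker genes and of an exchanged untreated column further on, were chosen only after the results were seen; the test of other BMP targets and the splits of the columns were set before theirs.

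The epidermal differentiation list was not called at 24 h (31 higher and 17 lower, median 0.08, adjusted p = 0.76). Picked keratinocyte genes had values of 1 sign in all 3 sizes there, as single columns without a test, and the lower ones go against most of the list. The transcription factor GRHL3, which acts in epidermal differentiation, was at -0.76, -0.72 and -0.55 for T-7, T-20 and T-200, the cornified envelope gene SCEL at -0.52, -0.47 and -0.57 and the keratin KRT13 at -0.41, -0.42 and -0.61. SPRR2D, a small proline-rich envelope protein, was at 0.93, 0.75 and 0.29, and the AP-1 gene JUND at 0.93, 0.90 and 0.55. Others differed between sizes. CST6, an epidermal cysteine protease inhibitor, was at 1.53, -0.14 and -0.16 at 24 h and CALML5, a calmodulin-like skin protein, at 1.19, -0.16 and -0.40. The neutrophil chemokine CXCL8 was at -1.17, 0.25 and 0.74 at 6 h and the differentiation factor ZNF750 at -1.02, 0.32 and 0.56. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was at -0.45, -0.44 and -0.48 at 2 h. AQP3, the glycerol channel of the epidermis, was at -0.26 (SE 0.06) for the mean of the sizes in limma and did not pass (adjusted p = 0.50). Cytosolic ribosomal proteins had a median of 0.23 for T-7 at 6 h (40 of 44 higher) and -0.07 at 2 h (41 of 44 lower), and histone genes a median of 0.23 for T-200 at 2 h (19 of 24 higher).

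ID1, ID2, ID3, ID4 and DLX2 had lower values in all 9 TiO2 columns. In T-7 minus T-200, which does not use the control, the mean of the 5 genes was -1.18 (SE 0.18 over the 3 times, with -0.84, -1.25 and -1.46). However, ID1, ID2, ID3 and DLX2 were picked because T-7 minus control called them, and this difference uses the same T-7 columns. That choice pulls it below 0, so by itself it cannot decide on a deviating control column as the whole cause. T-20 and T-200 share the control columns and leave out T-7. At 2, 6 and 24 h ID2 was at -1.24, -1.72 and -1.51 with T-20 and -0.70, -1.01 and -0.78 with T-200. All 5 genes were lower with T-20 at each time, without a test, but ID4 at 2 h barely (-0.79 against -0.74). Only DLX2 was itself called for T-20. For these 5 genes this argues against a deviating control column as the whole cause, though not as a part of it. A shift of the whole column is too small and of the other sign, since the median of all named genes in the T-7 columns was 0.02, 0.08 and 0.09. Median centring moves values by no more than that, so the mean of T-7 minus control after it, -2.05 (SE 0.22), was bound to stay far from 0. Lower BMP and SMAD signalling is a hypothesis that other BMP targets left undecided: their median lay at percentile 19.5 of random lists, 6 of 11 were lower with a list median of -0.01, HEY1 (-1.01) and GATA2 (-0.59) were lowest, and TBX2 (0.51) and SMAD9 (0.47) highest. Centrifugal fraction differed with particle size, the sources do not say whether dose or aggregate size did, and all of these stay open for the difference between sizes.

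Cholesterol synthesis genes were higher at 24 h with each size. A shift of the whole column is too small, with medians of all named genes of 0.08, 0.06 and 0.02 for T-7, T-20 and T-200, against 0.46 or more for the list. The list, picked as the group of largest change, lay at percentile 100 of random lists in all 3 sizes. A deviating untreated column of 24 h cannot be told apart from an effect of TiO2, since the 3 sizes share that column and the smallest of their medians was 0.46. An effect of the particles on sterol synthesis is thus a hypothesis that a second untreated culture of 24 h would test.

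Fibroblast markers were called higher with T-7 (adjusted p = 0.0079, and 0.95 with an estimated correlation), and markers of other cell types had positive medians without a call. Fibroblasts mixed into the cultures cannot be told apart from a change within the cells by the collagens: the mean of COL1A1, COL1A2 and COL3A1 minus the median of leukocyte, endothelial and melanocyte markers was -0.02 (SE 0.11), with COL1A1 at -0.78, -0.14 and 0.76, COL1A2 at 0.72, 0.38 and 0.79 and COL3A1 at 0.17, -0.14 and 0.11 at 2, 6 and 24 h. They went both ways, and their level in these cells is not known. An upward drift shared with probes that have no gene symbol stays open for the leukocyte, endothelial and melanocyte markers: over the 9 TiO2 columns their median minus that of these probes was 0.03 (SE 0.02, from -0.06 to 0.14), within 2 SE of 0, beside a mean of 0.13 for the probes themselves. That SE takes columns that share a control column as independent. For T-7 alone the gap was above 0 at each time (0.05, 0.05 and 0.04 at 2, 6 and 24 h). The probes themselves had medians of 0.10, 0.14 and 0.30 there. No biological explanation was tested for this pattern.

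Other splits of the columns were fitted for every comparison. For the mean of the sizes against control, these exchanged columns within each time. As many probes were called in 1 of 64 splits (7, highest other 2) and as many genes in 2 of 64 (2, highest other 2). For lists it was 14 of 64 (13, highest other 19). The shares for probes and genes lie under 0.05 but were not corrected for the number of comparisons split, so they do not exclude chance. The other comparisons had 10 splits of 3 columns against 3, too few for a share under 0.05, and most of these put 2 columns of the same time on one side. Only 4 exchange columns within times alone, and among these the highest other was 0 probes and 0 genes for every comparison, with as many lists or more in 4 for T-7 minus control, 1 for T-20 minus control, 2 for T-200 minus control, 4 for T-7 minus T-200, 3 for T-7 minus T-20 and 2 for T-20 minus T-200. For T-7 minus control the counts were 13 probes (highest other 0), 5 genes (0) and 7 lists (13, as many in 9 splits). For T-20 minus control they were 0 probes (0), 1 gene (0) and 13 lists (9). For T-200 minus control they were 0 probes (0), 0 genes (0) and 8 lists (14, as many in 6 splits), with 2263 probes and 1114 genes at an unadjusted p under 0.05 in limma. For T-7 minus T-200 they were 0 probes (0), 0 genes (0) and 11 lists (16, as many in 6 splits), for T-7 minus T-20 0 probes (0), 0 genes (0) and 10 lists (17, as many in 7 splits), and for T-20 minus T-200 0 probes (0), 0 genes (1) and 5 lists (9, as many in 8 splits). In the model with a TiO2 term per time, each TiO2 column was set apart in turn in place of the untreated one, 4 choices per time and 16 for the difference between 24 h and 2 h, too few for a share under 0.05. The real counts of genes were 9 at 2 h (highest other 14, as many in 2), 1 at 6 h (32, in 3), 34 at 24 h (34, in 2) and 6 for the difference (88, in 6). The counts of 32 and 88 are several times the real ones, and whether a structure of the columns or outlying single genes gave them was not tested.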
